A study of Mus musculus with 2 samples.

How the data were processed

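The data were DNase-seq of kidney tissue from 14-day-old male B6CASTF1/J mice. Per the labels, there were 2 libraries, biological replicates 1 and 2 of 1 group, with the same donor identifier. Per the labels each sample also mentions 3 males, and whether each library pools the kidneys of several animals is not given in the sources used here. The labels name Illumina instruments for replicate 1 and none for replicate 2. Per the file headers, reads were aligned to mm10 (GRCm38) and filtered, and every file was made from the alignments of a single library. The aligner, the peak and footprint callers and their versions are not given, nor is the handling of reads that carry CAST/EiJ alleles, although mm10 is a C57BL/6J sequence. Unplaced contigs and the mitochondrial genome do not occur in the files.

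Each library had 2 deposited peak lists whose signal column, the peak strength, was made by the authors on a scale that is not stated. Its values under 3 were whole multiples of a single step per library within 0.05 of a step (100% of 176202 and 120188 values tested), so a constant per library had been applied. Strength was therefore used as a rank, a percentile within its own list, except in the ratios and halved strengths for the X chromosome. Those assume that strength is proportional to the number of cuts, which is not stated. A checked property told the lists apart. In the stricter list every peak held a base with a deposited q-value (false discovery rate, FDR) under 0.001, and in the looser list the limit was 0.05. The authors also deposited a file of FDR values, used here as q-values, which lists only bases under 0.05. In the deposited footprint files the p-value column holds 0.01 in every line, which is a calling threshold and no score per footprint. The text file that lists each library's files held no measurement and was not used.

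Peaks of the stricter lists were used throughout. A peak counted as shared when it overlapped a peak of the other replicate by at least 1 bp, and shared peaks are given by the coordinates of replicate 1. The smallest FDR in each peak and the overlap of FDR bases were taken with bedtools 2.31.1, and everything else, peak overlaps included, was computed in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Genes and transcription starts came from GENCODE M21, with 21938 protein-coding genes on chromosomes 1 to 19, X and Y, and sequence came from the RefSeq copy of GRCm38. A gene was open when a peak lay within 1000 bp of any of its annotated starts in both replicates. Its strength is that of its strongest promoter peak in each replicate, which can be a different peak in each. That peak can lie at an internal start, over 1000 bp from the gene's 5′ end. Distal peaks lay farther than 1000 bp from every protein-coding start, and a locus was the gene with 50 kb on each side.

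The comparisons, gene lists, consensus sequences and alternatives were chosen before the data were examined, except where the text says otherwise. The 22 gene lists were those of the kidney's cell types, kidney transcription factors, proliferation and housekeeping genes, neighbouring or contaminating tissues, and olfactory receptors taken by symbol. Of 331 symbols fixed in the other lists, 330 were matched. Open promoters were compared with all other protein-coding genes by two-sided Fisher's exact tests. Distal peaks per locus were compared with 10000 random lists matched on decile of locus length, with two-sided permutation p-values. Both were adjusted over the 22 lists by the method of Benjamini and Hochberg, at a threshold of 0.05, as were the 28 consensus sequences below. Genes, not mice, were the units of these tests.

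Peak location was compared with 100 shuffles of the peaks within each chromosome outside assembly gaps, with classes assigned in the order promoter, exon, intron, intergenic. Footprints in peaks, with 5 bp added on each side, were searched on both strands for each consensus. The control was a window of the same length in the same peak that overlapped no footprint. Footprints for which none was found were left out, so the shares describe the others only. That left 348603 windows from 371853 footprints in peaks in replicate 1, and 230976 from 253838 in replicate 2. A consensus was called when both libraries passed a two-sided Fisher's exact test in the same direction. Intervals of ratios are exact 95% intervals. Where the control count was 0, the ratio was taken against a floor of 3 counts per library. The lower limit of the exact interval, from the counts themselves, is then given beside it. Density on X was taken per Mb outside gaps, and strengths on X were compared by a two-sided permutation test with 100000 resamples. Shares of peaks have exact (Clopper-Pearson) 95% intervals. Since the depth is unknown, no floor on accessibility could be given.

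Genes named in the text follow a rule. For each list that passed a test, and for the kidney transcription factor, proximal tubule, podocyte and nephron progenitor lists whatever their result, these are the 3 members with the strongest promoter peaks, the 2 with the most distal peaks, and the first 2 in alphabetical order without a promoter peak in either replicate. The 5 loci with the most distal peaks, the 5 strongest shared peaks and the called consensus sequences with the 5 highest and 3 lowest ratios were also named. Not every gene that the rule picks is described. Other names are marked as chosen after their values were seen.

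The alternatives were peaks shared by 50% reciprocal overlap, the strongest 50000 peaks, the looser lists, promoter windows of 500 and 2000 bp, the gene's 5′ end only and loci of 10 kb. For footprints they were no added bases, footprints shared between libraries and the reversed consensus as the control. Each replicate was also left out in turn. The procedures were tested on simulated data. In 20 simulations, 38 of 40 planted promoter lists and 20 of 20 planted distal lists were called, against 2 of 380 and 0 of 400 other lists. Outside the planted lists, simulated genes were equally likely to be open whatever their CpG content, and only larger lists were planted. These rates need not hold for small lists or for promoters that differ in CpG content. In 200000 simulated windows, 2 of 2 planted consensus sequences and 0 of 25 others were called. Allele-specific accessibility was not analysed here, since the files hold no alleles.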

Results

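DNase-seq, which maps chromatin that the nuclease DNase I can cut, was carried out on the kidney of 14-day-old male B6CASTF1/J mice, the first-generation cross of C57BL/6J with the wild-derived strain CAST/EiJ. The labels give 1 group with 2 biological replicates, and each label mentions 3 males. Replicate 1 had 126326 peaks of accessible chromatin in the stricter of its 2 deposited lists, with a median width of 200 bp and 25.4 Mb in all. Replicate 2 had 92868 peaks, with a median width of 180 bp and 17.7 Mb in all. The looser lists held 192296 and 140653 peaks. Footprints, short stretches protected from cutting inside accessible DNA, numbered 562326 in replicate 1 and 364995 in replicate 2. Read totals are not given in the sources used here, so the depth is unknown. The peak strengths rose in steps of 0.00409 in replicate 1 and 0.00720 in replicate 2. The scale behind these steps is not stated. All intervals given here cover counting error only. With a single group, no difference between groups could be tested. The comparisons asked which genes were accessible, where the peaks lay, which recognition sequences the footprints held, and how far both replicates shared these features.

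Of 21938 protein-coding genes, 14617 (66.6%) had a promoter peak in both replicates, which is called open here; 692 had one in replicate 1 alone and 54 in replicate 2 alone. Among transcription factors that pattern the nephron, 28 of 29 were open, and the exception, Foxi1 of intercalated cells, had a promoter peak in 1 replicate. The strongest belonged to Esrra, which encodes the oestrogen-related receptor of mitochondrial genes (ENSMUSG00000024955.14). Its promoter peak at 19:6921801–6922080 (GRCm38) had a strength percentile of 99.96 ± 0.023 (mean ± SD, n = 2), where 100 is the strongest peak of a library. The fatty acid oxidation regulator Ppara followed at 96.6 ± 1.97 and the proximal tubule factor Maf at 94.7 ± 1.78. Pax2, needed for the first steps of kidney development, was open at 79.1 ± 8.84, and the nuclear receptor gene Esrrg at 77.6 ± 7.59. The peak of Esrrg lay at an internal start. Across all open genes the median percentile was 92.1, so a high value is usual for an open promoter. The open genes of kidney transcription factors (median 86.5), endothelial (78.7), proximal tubule (76.6), podocyte (73.8) and nephron progenitor lists (69.2) lay below it. Those of the housekeeping (97.2) and proliferation lists (94.1) lay above it.

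Endothelial genes were open in all 19 cases. Ehd3, a marker of glomerular capillaries, had the strongest promoter peak of them (94.1 ± 0.90; 17:73804641–73804920). Esam, a junctional adhesion gene, reached 89.4 ± 2.82, and Eng, a co-receptor for TGF-beta ligands, 88.5 ± 0.74. The vascular growth factor receptor gene Flt1 was open at 82.8 ± 4.81 and the secreted factor gene Egfl7 at 82.7 ± 2.73. The peaks of Esam and Egfl7 lay at internal starts.

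Of 34 proximal tubule genes, which serve reabsorption from the filtrate, 27 were open. Acy3, an aminoacylase, was strongest (96.8 ± 0.58; 19:3986381–3986580; ENSMUSG00000024866.10). The neutral amino acid transporter Slc6a19 followed at 94.2 ± 1.74, from a peak at an internal start and not at its 5′ end. The endocytic receptor Lrp2, megalin, stood at 89.2 ± 2.94. Pck1, which makes glucose from lactate and amino acids, stood at 88.9 ± 3.45. The urate transporter Slc22a12 had a weaker promoter peak that differed between replicates (48.1 ± 19.99). Dpys, a pyrimidine-degrading enzyme, and Slc22a8, an organic anion transporter, had no promoter peak in either replicate.

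Podocytes, the filter cells of the glomerulus, had 15 of 17 marker genes open. The actin-binding Synpo (92.7 ± 0.68) and the cell-cycle inhibitor Cdkn1c (92.4 ± 2.27) were among the strongest of these, near the median of 92.1 of all open genes. The peak of Synpo lay at an internal start. The basement membrane collagen Col4a4 stood at 80.8 ± 8.02.

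Nephron progenitor and ureteric tip genes, which act before birth and in the first days after it, were open in 13 of 15 cases. Sall1 (87.8 ± 4.88), Wnt11 (86.9 ± 3.05, at an internal start) and Lhx1 (84.1 ± 4.66, from peaks that did not overlap between replicates) had the strongest peaks. Meox1 stood at 61.1 ± 0.024. Fgf8 had no promoter peak. The progenitor factor Six2, chosen after its values were seen, was open at percentiles 48.3 in replicate 1 and 31.8 in replicate 2.

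By Fisher's exact test (two-sided, against all other protein-coding genes, adjusted over the 22 lists), 3 lists were open more often than other genes. By this exact test these were kidney transcription factors (96.6%, adjusted p = 0.00117), endothelial genes (100%, adjusted p = 0.00304) and housekeeping genes (18 of 18, adjusted p = 0.00304), where Rplp0 reached 99.9 ± 0.13, Eef2 99.7 ± 0.12, Ppia 99.5 ± 0.072 and Actb 99.4 ± 0.40. The calls of kidney transcription factors and housekeeping genes ended against random lists matched on promoter CpG count (adjusted permutation p = 0.180 and 1), a comparison chosen after seeing the data. Counting only the gene's 5′ end ended the endothelial and transcription factor calls (adjusted p = 0.243 and 0.112, Fisher's exact test). The endothelial call also ended with the strongest 50000 peaks (84.2%, adjusted exact p = 0.0668).

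Proximal tubule (adjusted p = 0.199), podocyte (0.114) and nephron progenitor genes (0.217) did not pass Fisher's exact test, nor did thick ascending limb genes (11 of 12, 0.114) such as the Tamm-Horsfall protein gene Umod. The distal convoluted and connecting tubule list (8 of 10, 0.563), principal cells (11 of 12, 0.114), intercalated cells (8 of 13, 0.804) and stromal and mural cells (14 of 17, 0.251) did not pass either. Proliferation genes were open in 10 of 10 cases (0.0814). Some of these passed the exact test under an alternative. Podocyte genes passed with the looser lists (100%, adjusted p = 0.00745, Fisher's exact test) and without replicate 1 (94.1%, 0.0431), and stromal and mural genes with the looser lists (100%, 0.00745). Without replicate 2, proximal tubule genes (91.2%, 0.010) and principal cell genes (100%, 0.0426) passed. Proliferation genes passed with a window of 500 bp (0.0365) and with the strongest 50000 peaks (0.0178). Against random lists matched on CpG count, proximal tubule genes (79.4% against 47.7% ± 6.78) and thick ascending limb genes (91.7% against 41.2% ± 11.4) were open more often. So were endothelial genes (100% against 65.0% ± 8.68). Each had a permutation p of 0.0002, the smallest the random lists can give, and 0.00088 after adjustment. No other list of kidney cell types passed there. Podocyte genes (88.2% against 86.4% ± 7.06) and nephron progenitor genes (86.7% against 90.4% ± 6.90) were close to their random lists.

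Immune genes were open in 4 of 20 cases (adjusted p = 0.000278, lower, Fisher's exact test). The open ones were Coro1a, an actin regulator of leukocytes (90.6 ± 0.54), the myeloid factor Spi1 (48.1 ± 5.18), the endotoxin co-receptor Cd14 (43.6 ± 7.57) and the lysozyme gene Lyz2 (35.8), which was chosen after its values were seen. The peak of Coro1a lay at an internal start. The macrophage genes Adgre1, Aif1, Csf1r and Cx3cr1 had no promoter peak. Spermatogenesis and oocyte genes were open in 2 of 14 cases (adjusted exact p = 0.000607, lower), namely Dazl (88.0 ± 5.15) and Sycp3 (10.9 ± 9.79; 17.8 in replicate 1 and 3.96 in replicate 2). Acrv1, Ddx4, Prm1 and Stra8 were closed. Olfactory receptor genes were open in 14 of 1135 cases (1.23%, lower), with Olfr433 strongest (72.0 ± 6.21), followed by Olfr15 (43.0 ± 14.6) and Olfr373 (42.6 ± 5.15). The peaks of Olfr15 and Olfr373 lay at internal starts.

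Adrenal genes, listed because the gland lies on the kidney, were open in 3 of 12 cases (adjusted p = 0.0107, lower, Fisher's exact test). These were the chromaffin granule gene Chga (85.1 ± 0.53), the steroidogenic gene Star (51.4 ± 4.03) and its regulator Nr5a1 (23.2 ± 6.94, at an internal start), while Cyp11a1, Cyp11b1 and Pnmt were closed. Hepatocyte genes were open in 5 of 15 cases (adjusted exact p = 0.0264, lower): Apob (73.3 ± 2.66), Fga (60.1 ± 6.30), Apoa2 (51.6 ± 9.24), Cyp8b1 (43.8 ± 8.34) and, named after its values were seen, Apoc3. Ahsg and albumin, Alb, were closed. Striated muscle genes were open in 5 of 17 cases (adjusted exact p = 0.00909, lower). Among these were Mylpf (96.0 ± 2.33), Actn3 (96.0 ± 0.18) and Ckm (87.4 ± 1.60), and Acta1, Myf5, Myog and Tnnt2 were closed. For Mylpf and Ckm the strongest promoter peak of each replicate was a different one, without overlap. Against random lists matched on CpG count, the calls ended for immune genes (20% against 37.3% ± 9.89, adjusted permutation p = 0.268) and muscle genes (29.4% against 50.1% ± 11.1, 0.268), although both shares stayed below those of the random lists. They also ended for adrenal genes (25% against 39.2% ± 9.98, adjusted permutation p = 0.549) and hepatocyte genes (33.3% against 27.8% ± 10.8, 1). The adrenal call also ended without replicate 1 (0.0572, Fisher's exact test). The hepatocyte and muscle calls ended with a promoter window of 2000 bp (0.0516 and 0.0509), and the hepatocyte call with the gene's 5′ end only (0.0755).

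Urothelial genes were open in 3 of 8 cases (adjusted p = 0.186, Fisher's exact test), adipocyte genes in 5 of 10 (0.368), neuronal genes in 12 of 17 (0.804) and erythroid genes in 4 of 11 (0.101). Urothelial genes passed as lower with a window of 500 bp (12.5%, adjusted p = 0.0112, Fisher's exact test). Erythroid genes did so with the strongest 50000 peaks (18.2%, exact p adjusted 0.0220), with the looser lists (0.0397) and without replicate 2 (0.0426). The share of open promoters rose with CpG content, from 2.0% in the lowest decile of promoter CpG count to 97.3% in the highest.

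**Figure D1:**
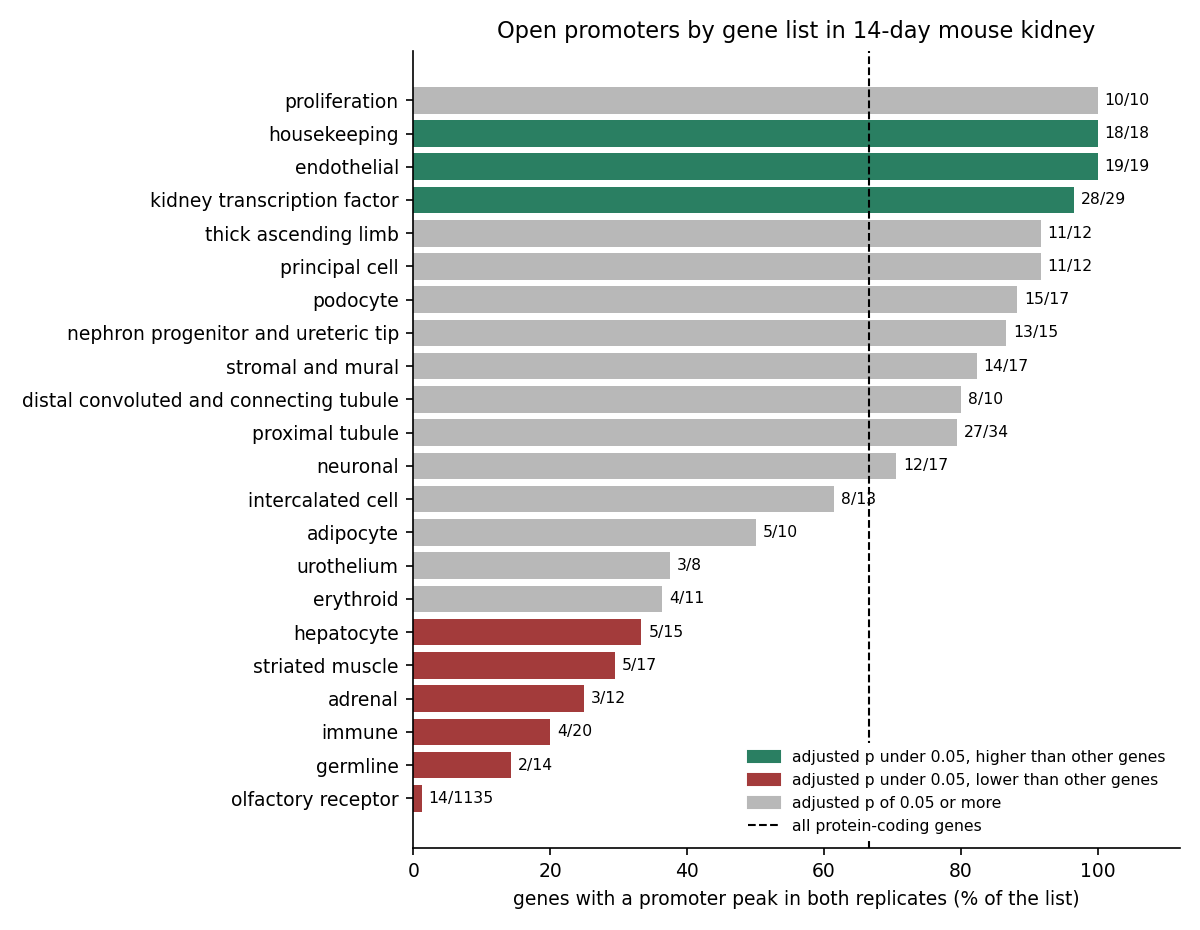
Each bar gives the percentage of a list's genes that had a promoter peak in both replicates, with the counts beside it, and the dashed line marks the 66.6% of all protein-coding genes. Endothelial and housekeeping promoters were all open, while olfactory receptor promoters were open in 1.23% of cases.

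Distal peaks, those over 1000 bp from any protein-coding transcription start, numbered 59978 among the peaks found in both replicates. The median gene had 4 of them within 50 kb, and 16.7% of genes had none. Esrrg had 25 and Pax2 had 20, the most among the kidney transcription factors. Flt1 (17) and Egfl7 (16) led the endothelial genes, Pck1 (16) and Slc22a12 (14) the proximal tubule genes, and Col4a4 (13) and Synpo (12) the podocyte genes. Slc22a8 had 13 distal peaks despite its closed promoter. The same held for the macrophage genes Cx3cr1 (18) and Csf1r (11), the adrenal genes Pnmt (17) and Cyp11a1 (11), and the muscle genes Myog (11) and Tnnt2 (11). Some of these peaks lie in or beside neighbouring genes, so they need not belong to the gene named. Meox1 had 17, Cyp8b1 had 9, and Prm1 and Stra8 had 6 each, as did Olfr222, while Olfr1368 had 9.

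Against 10000 random lists matched on locus length (two-sided permutation test, adjusted over 22 lists), 2 lists differed. Housekeeping genes, led by Actb (19) and Rplp0 (16), had 1.82 times the mean number of distal peaks of the random lists (7.61 against 4.17, adjusted permutation p = 0.0176). Olfactory receptor genes had 0.12 times theirs (0.448 against 3.74), with a permutation p of 0.0002, the smallest these permutations can give, and 0.0044 after adjustment. Kidney transcription factors (ratio 1.62, adjusted permutation p = 0.0543), endothelial genes (1.67, 0.0748), proximal tubule genes (1.30, 0.228) and thick ascending limb genes (1.45, 0.256) did not pass. The housekeeping call ended with the looser lists (ratio 1.58, adjusted permutation p = 0.0865) and with loci of 10 kb (1.56, 0.376). It also ended without replicate 2 (1.53, 0.116) and among open genes alone (1.41, 0.177). Transcription factors passed with the strongest 50000 peaks (1.87, 0.0352) and without replicate 2 (1.79, 0.0418), and germline genes at 10 kb (0.185, 0.0110).

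The loci with the most distal peaks were long gene models. Gm20388, a readthrough model of 4435 kb on chromosome 8, held 336, and Fgfr2, whose annotation spans 2961 kb, held 146. Lrmda (69), Gse1 (63) and Pde4d (57), which encodes a cyclic AMP phosphodiesterase, followed. Gse1 was the densest, with 13.9 distal peaks per 100 kb.

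At Pck1, an HNF1 consensus, the sequence bound by the hepatocyte nuclear factor 1 proteins of the proximal tubule, lay in an intergenic peak 23714 bp from the gene. The site, TTAATGATTAAC at 2:173129334–173129345, was partly overlapped by footprints in both replicates. These were 173129330–173129338 and 173129340–173129355 in replicate 1, and 173129343–173129349 in replicate 2. The site was chosen after its values were seen.

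**Figure D2:**
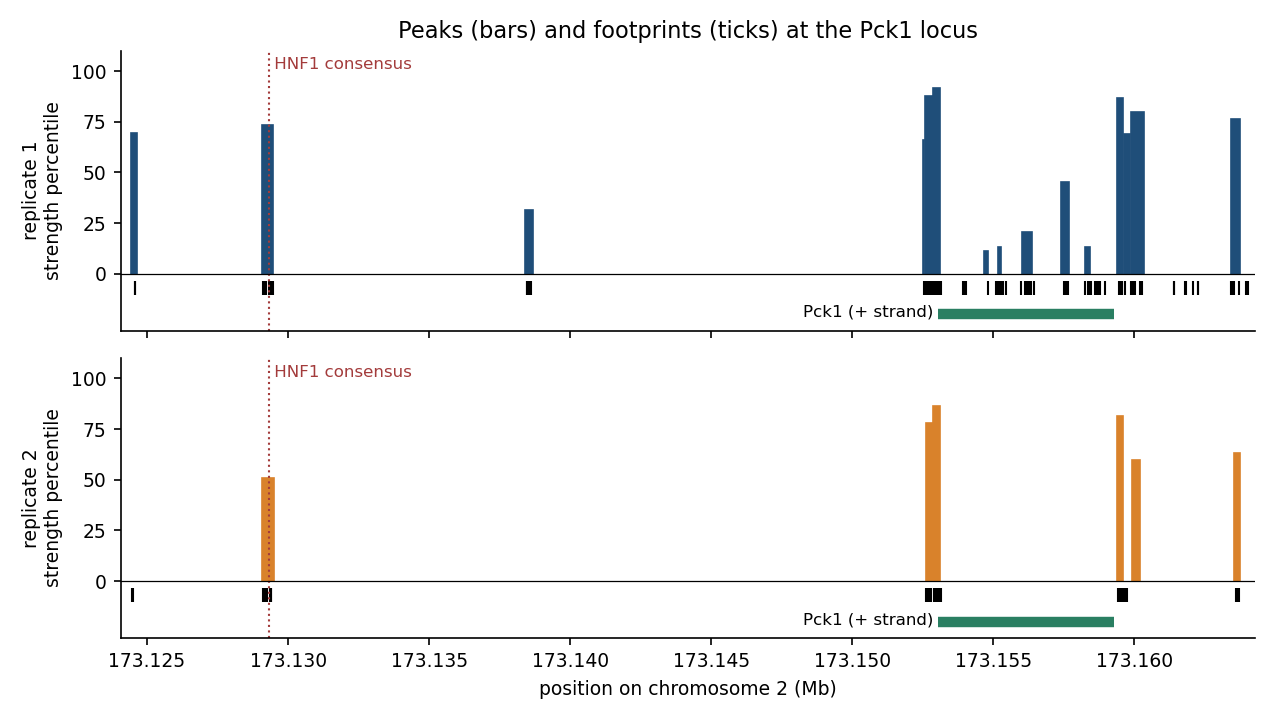
Bars mark the peaks around Pck1 on chromosome 2 at their strength percentile (y axis) and position in Mb (x axis), ticks the footprints, and the dotted line the HNF1 consensus, with replicate 1 above and replicate 2 below. The window holds 15 peaks and 83 footprints of replicate 1 and 6 peaks and 28 footprints of replicate 2.

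Footprints were tested for 28 consensus sequences, and 17 were more frequent and 6 less frequent in both libraries than in footprint-free windows of the same peaks (two-sided Fisher's exact test, adjusted over the 28). CTCF, the insulator protein, had its consensus in 1.55% of the windows of replicate 1 and 1.95% of those of replicate 2, which was 87.7 ± 12.2 times the control share (mean ± SD, n = 2). NFI, a dimer whose Nfia and Nfib members act in the kidney, stood at 68.1 ± 17.2. SP/KLF, the GC box of many promoters, stood at 18.5 ± 4.68 and CRE, the cyclic AMP response element, at 17.8 ± 12.2 (26.5 in replicate 1 and 9.17 in replicate 2). For REST, the repressor of neuronal genes, control windows were few. With 3 of them, the ratio was 68.0 in replicate 1 (95% interval 22.9 to 332), and with 1 control window it was 209 in replicate 2 (37.1 to 8294). Windows with the NRF1 consensus, a site of nuclear genes for mitochondrial proteins, numbered 263 in replicate 1 against 0 in the control. Against a floor of 3 control counts per library the ratio was 87.7, and its exact 95% interval starts at 70.8. In replicate 2 they numbered 240 against 1 control window (ratio 240, 95% interval 42.7 to 9518).

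HNF1 had ratios of 22.0 (95% interval 7.21 to 109, 3 control windows) and 5.33 (1.53 to 28.6, 3 control windows). HNF4, which acts with it in the proximal tubule, stood at 3.38 ± 0.63. The direct repeat DR1, read by HNF4 and PPAR receptors, occurred in 20 and 7 windows against 0 in the control. Against the same floor the ratios were 6.67 and 2.33, and their exact 95% intervals start at 4.94 and 1.44. The DR1 call ended in replicate 2 against the reversed consensus (7 against 1, adjusted p = 0.0759, Fisher's exact test) and, after the data were seen, in distal peaks (0.0833) and promoter peaks (0.538) taken apart. The other sequences called higher were YY1 (3.43), ETS (3.24), ARE (2.64), TFAP2 (2.03), TFCP2L1 (1.55), the E-box CAGCTG (1.39), NFY (1.29) and RFX. With no bases added around footprints, YY1 (1.56, adjusted p = 0.106, Fisher's exact test) and NFY (1.06, 0.330) no longer passed in replicate 2. In the split by peak type, which leaves fewer windows, YY1 (ratio 2.83) and RFX no longer passed in distal peaks. Nor did HNF1, ARE (1.98) and TFCP2L1 (1.14) in promoter peaks. For HNF1 in promoter peaks of replicate 2 the count was 3 windows against 0 (adjusted p = 0.292, Fisher's exact test).

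FOX (0.312 ± 0.081), GATA (0.459 ± 0.088) and GRHL (0.550 ± 0.15) had the lowest ratios among the sequences called lower, which also included POU (0.60), TEAD (0.829) and RUNX (0.835). With fewer windows, the calls of POU (ratio 0.701) and RUNX (0.873) ended in distal peaks and that of TEAD (0.833) in promoter peaks. Against the reversed consensus in the same footprints, FOX (0.518) and GRHL (0.520) stayed lower, while the other directions depended on the control. TEAD (9.26), RUNX (2.43) and POU (24.5) turned higher, as did AP-1 (2.38) and MEF2 (4.40), which had not been called. Reversing can change the number of CpG sites, as in POU, so CpG content is not matched by this control. ESRR (2.49) and PAX2/8 (9 windows against 1 and 6 against 0) also passed as higher there, so that 22 of 27 sequences did. GATA (1.28) also turned, but did not pass in replicate 2 (ratio 1.20, adjusted p = 0.156, Fisher's exact test). The E-box turned lower (0.851) in promoter peaks. ESRR, PAX2/8, AP-1, MEF2 and the p53 family were not called, the last with 0 windows in either library, which allows a share of up to 0.000861% in replicate 1 and 0.00130% in replicate 2. AP-1 (0.906) passed as lower with no bases added (0.709), with footprints shared between libraries (0.797) and in promoter peaks (0.673). The tested windows were richer in GC than their controls, at 57.9% against 53.2% in replicate 1 and 60.2% against 54.0% in replicate 2.

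**Figure D3:**
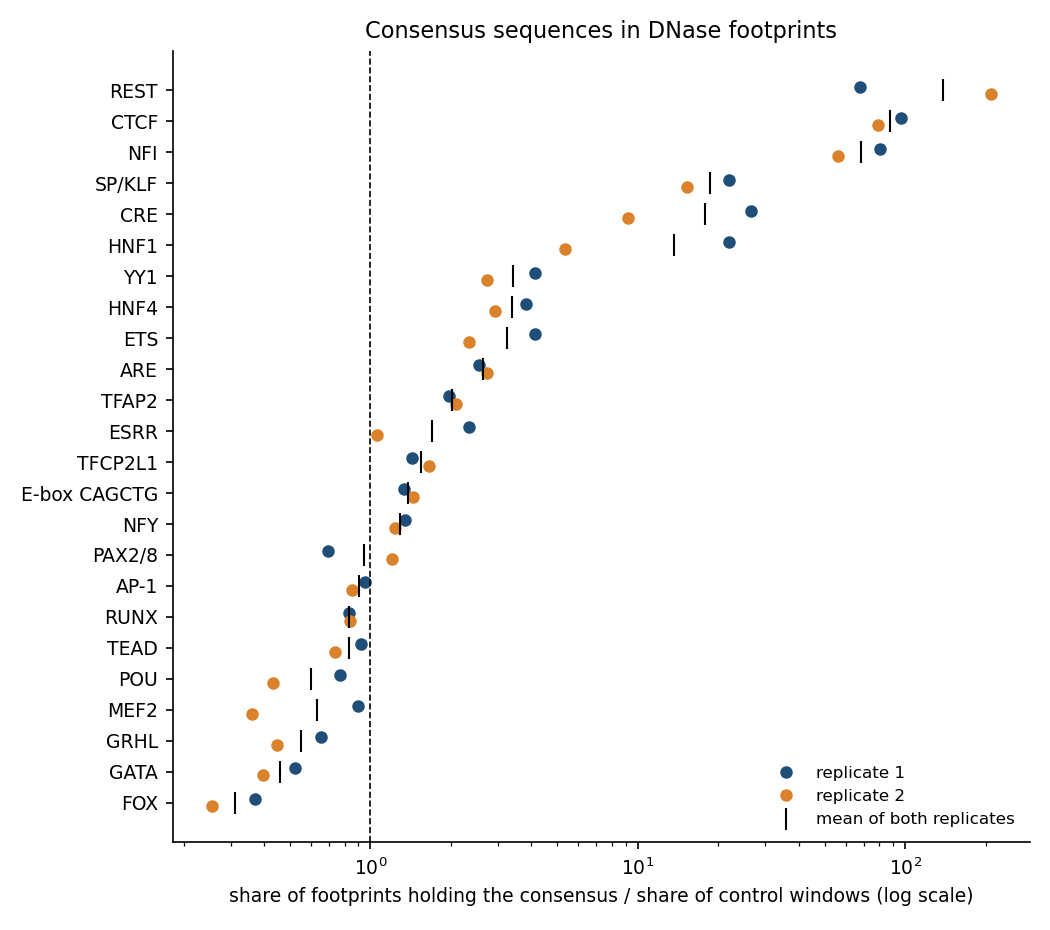
Points give, for each library, the share of footprint windows that held a consensus divided by the share of control windows, on a log axis, and black marks the mean of both. Sequences with 0 windows on either side in a library are not drawn, and CTCF, at 87.7 ± 12.2, sat far above FOX, at 0.312 ± 0.081.

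Peaks found in both replicates numbered 86163 by the coordinates of replicate 1. Promoters took 26185 of these (30.4%, exact 95% interval 30.1 to 30.7), 6.86 times the 4.43% ± 0.066 of peaks shuffled within each chromosome. Exons took 4.74% (1.16 times), introns 29.5% (0.868 times) and intergenic sequence 35.4% (0.615 times). Each class differed from the shuffles with a two-sided permutation p of 0.0198, the smallest that 100 shuffles can give. Promoter peaks were also the strongest, with a median percentile of 78.9 against 55.8 in exons, 51.8 in introns and 50.9 in intergenic sequence.

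Of the 5 strongest shared peaks, a pair lay at promoters. One was that of the dynein light chain gene Dynlt1b (17:6430001–6430180) and the other that of the centromere protein gene Hjurp (1:88277521–88277760). The strongest, X:143482981–143483140, was intergenic, 35530 bp from the nearest start, that of Pak3. The second, 17:39846781–39846900, lay in the RefSeq pseudogene Rn18s-rs5, which resembles 18S ribosomal RNA. The remaining peak, 9:123461901–123462100, lay in the last exon of Lars2, a mitochondrial leucyl-tRNA synthetase gene. Sequences of 20 bases from the peaks at Rn18s-rs5, Dynlt1b and Lars2 had a median of 2, 3 and 5 copies in the assembled chromosomes and mitochondrial genome of the reference. Unplaced contigs were not counted, so these are lower limits. The median was 1 for the other peaks of the 5 and for 95 of the 100 next in rank.

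The X chromosome, of which males have a single copy, held 1237 distal peaks, or 7.57 per Mb against 24.5 per Mb on autosomes (ratio 0.309). The lowest autosome, chromosome 3, had 18.0 per Mb and the highest, chromosome 11, had 37.8. The X-linked genes Hprt and Pgk1, read in the housekeeping list and chosen after their values were seen, were open at 90.2 and 94.1. X-linked distal peaks had a median strength percentile of 29.0, which was 23.1 below that of autosomal distal peaks. A two-sided permutation test over peaks gave p = 1e-05, the smallest that 100000 resamples can give, and peaks are not independent replicates. With the strongest 50000 peaks the density ratio was 0.142. The Y chromosome held 18 distal shared peaks, and 25 with promoters included.

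**Figure D4:**
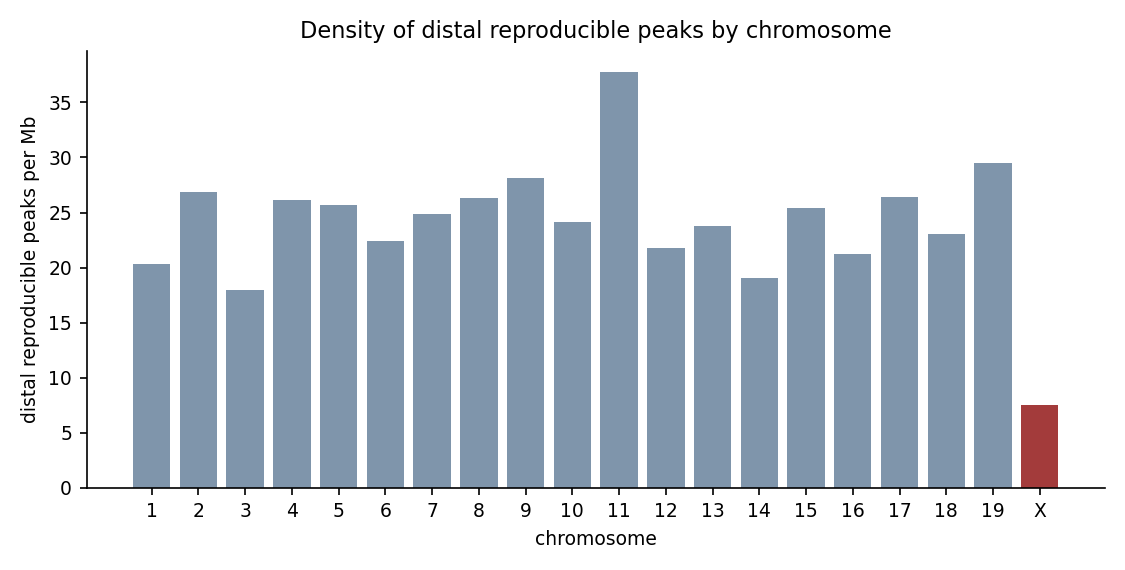
Bars give distal peaks found in both replicates per Mb of sequence outside assembly gaps, by chromosome. The X chromosome, in red, had 7.57 per Mb, below the 18.0 of chromosome 3.

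The strongest promoters were strong in both libraries. Esrra lay at percentiles 99.98 and 99.95, and Rplp0 at 99.8 and 99.97. In all, 86163 peaks of replicate 1 (68.2%, exact 95% interval 67.9 to 68.5) overlapped a peak of replicate 2, and 86470 peaks of replicate 2 (93.1%, 92.9 to 93.3) overlapped a peak of replicate 1. The Jaccard index of bases was 0.563. Across shared peaks, which are not independent replicates, Spearman's rho of strength was 0.943. In the top decile of strength, 99.4% of replicate 1 and 99.9% of replicate 2 peaks were shared, against 16.9% and 75% in the lowest decile. Bases with a false discovery rate under 0.05 covered 63.5 Mb in replicate 1 and 45.1 Mb in replicate 2, and 93.9% of the latter were also in the former.

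**Figure D5:**
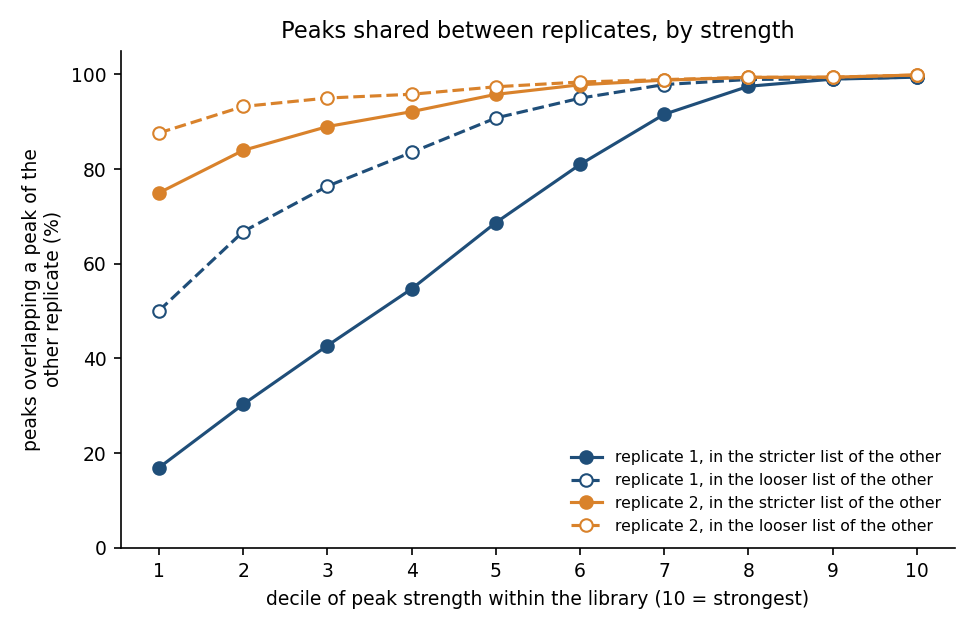
Lines give the percentage of peaks in each decile of strength that overlapped a peak of the other replicate, in its stricter list (filled) or looser list (open). In the lowest decile 16.9% of replicate 1 and 75% of replicate 2 peaks were shared with the stricter list.

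Footprints overlapped the HNF1 sites of Pck1 and of Slc7a7, a basolateral amino acid transporter chosen after its values were seen, at least in part in both replicates. The HNF1 site of the bicarbonate transporter Slc4a4, chosen in the same way, had a footprint in replicate 1 alone. In all, 43.0% of replicate 1 footprints overlapped a footprint of replicate 2, and 67.4% of replicate 2 footprints overlapped one of replicate 1. Inside peaks found in both replicates the shares were 62.9% and 73.7%, and outside them 21.2% and 52.9%.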

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

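The tests of this part were chosen only after the counts were seen. Footprints that lie outside every peak of their own library's looser list were used in no comparison of peaks or recognition sequences. Such footprints numbered 94355 in replicate 1 (16.8% of its footprints) and 55388 in replicate 2 (15.2%), which is signal in data outside the main measurement. Of these, 99.4% in replicate 1 and 99.5% in replicate 2 had their midpoint in bases with a listed false discovery rate under 0.05. In replicate 1, 36.2% of them overlapped a footprint of replicate 2, against 44.4% of the footprints inside the looser peaks. In replicate 2, 68.5% overlapped a footprint of replicate 1, against 67.2% inside. The design holds 1 group, so no biological explanation was tested.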

How the results depend on the processing

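Lists matched on promoter CpG count, the distal test among open genes, and footprints split into distal and promoter peaks were chosen after seeing the data; the other alternatives were planned. Location kept its direction and its side of the threshold in all 4 classes under all 5 alternatives, with promoter ratios from 4.64 to 9.79. The X chromosome kept a lower density under all 4 of its alternatives (ratio 0.142 to 0.35) and a lower strength (7.06 to 27.8 percentiles below autosomes).

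Overlap between replicates moved with its definition. With 50% reciprocal overlap it was 60.5% of replicate 1 and 82.3% of replicate 2 peaks, with the strongest 50000 peaks 89.1% and 89.2%, and with the looser lists 65.4% and 89.8%. Footprint overlap was 31.8% and 48.9% with 50% reciprocal overlap, which can only lower it. Spearman's rho was 0.916 in the stronger 0.5 of replicate 1's shared peaks and 0.915 in the strongest 50000 peaks, where the range of strengths is narrower.

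The number of lists open more often was 1 with the gene's 5′ end only, 5 with the looser lists and 4 to 5 with either replicate left out. The number open less often was 2 against lists matched on CpG count, where the hepatocyte list (33.3%) reversed to lie above its random lists. For distal peaks, the number of lists above random was 2 with the strongest 50000 peaks and 0 with the looser lists, with loci of 10 kb and among open genes. The number below was 2 at 10 kb, where germline genes joined olfactory receptors. Among single lists, 150 of 176 promoter values and 191 of 198 distal values kept direction and side, with 12 and 4 weaker and 13 and 3 stronger. For these changes the cause was not tested, except that matching on CpG count removes what CpG content alone would give.

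Against the reversed consensus, the sequences called lower fell to 2, FOX and GRHL. AP-1 (2.38), TEAD (9.26), RUNX (2.43), POU (24.5) and MEF2 (4.40) reversed to lie above it in both libraries, GATA (1.28) reversed without passing in replicate 2, and the E-box reversed to 0.851 in promoter peaks. The cause was not tested. SP/KLF reads the same reversed and was left out there. Of 158 values for single sequences with a ratio, 136 kept direction and side. DR1, which has none, lost its call against the reversed consensus, and YY1 and NFY lost theirs with no bases added, where 15 sequences were called higher. AP-1 was called lower with no bases added, among shared footprints and in promoter peaks. Among the strength percentiles of named genes, 366 of 476 values moved by less than the spread between replicates. These include the 68 values for each replicate left out, which could not move farther than that spread. With the strongest 50000 peaks 47 of 68 moved, and with the looser lists 39 of 68. The planned limit to the stronger footprints was not run, since the files give every footprint the same score. A peak missing from a stricter list need not be missing from the looser one: of the peaks of replicate 1 without a partner, 55.8% overlapped a peak of the looser list of replicate 2.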

Other observations

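The Hox genes, the comparison of distal with promoter peaks, HNF1 sites taken alone, TFAP2 sites at transcription factor loci and copy numbers were tested only after their results or related ones were seen. Bounds for the other explanations below were set before their outcomes were computed, those for the X chromosome after its low peak density was known.

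Among 39 Hox genes, which give cells their position along the body axis, 30 had a promoter peak in both replicates. Hoxc5 and Hoxc10, which share their strongest promoter peak, had the highest mean strength percentile (96.7). Hoxa7 (96.6), Hoxa10 (95.9) and Hoxa9 (94.7) followed, and Hoxd10 stood at 92.3. Hoxa11 (68.1) and Hoxd11 (57.0), which together are needed for kidney formation, were weaker. Of the posterior group 13, Hoxa13, Hoxb13 and Hoxd13 had a promoter peak in replicate 1 alone, while Hoxc13 had one in both (78.8). Hoxb8, Hoxc4, Hoxc11, Hoxc12 and Hoxd12 had none.

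Distal and promoter peaks held different recognition sequences. The CTCF consensus lay in 11.8% of distal and 3.05% of promoter peaks, a ratio of 3.87. HNF1 (2.66), NFI (2.56), TEAD (2.12), HNF4 (1.92) and AP-1 (1.87) were also more frequent in distal peaks. YY1 (0.0381), NRF1 (0.0854), SP/KLF (0.127), ETS (0.145) and NFY (0.284) were more frequent in promoter peaks, as was TFAP2, in 10.3% of distal and 24% of promoter peaks. The reversed sequences, which keep base composition but not CpG count, were also uneven. Their ratios were 1.36 for TEAD, 1.30 for HNF4 and 1.60 for AP-1, and 0.109 for YY1, 0.218 for NRF1 and 0.0873 for TFAP2. For CTCF (0.249), NFI (0.107) and ETS (1.95) the reversed sequence went the other way. Reversing adds CpG sites to CTCF and NFI and removes that of ETS, so these ratios do not exclude an effect of CpG content.

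At the loci of proximal tubule genes, which HNF1 and HNF4 proteins drive, 5 of 220 distal peaks had an HNF1, HNF4 or DR1 consensus (2.27%) against 1.11% elsewhere, with an odds ratio of 2.08 (95% interval 0.666 to 4.95; two-sided Fisher's exact p = 0.0998). With 5 peaks, an excess and its absence cannot be told apart, so a bound that asked only for a p under 0.05 was too weak to exclude one. Base composition stays open as well: the reversed sequences occurred in 0 of 220 peaks. A floor of 3 counts allows a share of up to 1.36%, and separately the exact 95% interval of the odds ratio reaches 10.4. HNF1 alone lay in 3 of the 220, at Pck1, Slc4a4 (TTAATAATTAAC) and Slc7a7 (GTTAATCATTAA), 12.7 times the share elsewhere (p = 0.00196, adjusted 0.0486, Fisher's exact test). HNF4 alone lay in 2 of the 220 (0.924 times, exact p = 1) and DR1 in 0, so the choice of HNF1 from the combined set was favourable, and its excess may not recur in other data.

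ETS sites at endothelial loci, a candidate source of endothelial accessibility, occurred in 0 of 199 distal peaks. A floor of 3 counts allows a share of up to 1.51%, and separately the exact 95% interval of the odds ratio reaches 11.3. An excess and its absence thus cannot be told apart at this count. TFAP2 sites at distal nephron loci, where Tfap2a and Tfap2b act, lay in 31 of 260 distal peaks (11.9% against 10.3%, odds ratio 1.18, 95% interval 0.783 to 1.72), which likewise decides nothing.

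TFAP2 sites at the loci of kidney transcription factors lay in 48 of 243 distal peaks (19.8% against 10.3%, adjusted p = 0.00104, Fisher's exact test). Nephron progenitor and ureteric tip loci, which share Pax2 and Lhx1 with that list, passed too (21 of 99, 21.2%, adjusted p = 0.0422, Fisher's exact test). Shares were also above 10.3%, without passing, at principal cell (17.2%), housekeeping (16.8%), podocyte (16.5%), endothelial (16.1%), thick ascending limb (15.5%), immune (12.9%) and proliferation loci (12.3%). They were lower at stromal and mural (10.26%), distal convoluted and connecting tubule (9.26%), proximal tubule (8.18%) and intercalated cell loci (7.79%). Whether the excess is particular to transcription factor loci was not tested. Against peaks matched on GC content to those of the transcription factor loci, the share was 13.2% ± 2.15 (two-sided permutation p = 0.0052). The reversed sequence was also more frequent at the transcription factor loci (5.76% against 1.78%), by a larger ratio (3.24) than the sequence itself (1.93). These tests counted peaks as independent, although many share a locus, so the p-values may be too small.

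Fewer genes on X do not account for all of its lower density of distal peaks, since X had 1.30 distal peaks per protein-coding gene, below the 1.74 of the lowest autosome, chromosome 7. A partial contribution was not excluded. A single copy in males may contribute, if strength is proportional to the number of cuts, which is not stated: distal peaks with a CTCF consensus had 0.484 times the autosomal median strength in replicate 1 and 0.466 times in replicate 2, near the 0.5 that 1 copy would give. Across all distal peaks the ratios were 0.60 and 0.604, and at promoters 0.581 and 0.607, farther from 0.5. On the same assumption it is not the whole difference, since X still had 0.362 times the density of autosomes whose peak strengths were halved and held to the same floor. What adds to it stays open, and no comparison with females was possible.

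Replicate 1 had more peaks than replicate 2. Greater depth of replicate 1 is a candidate cause, and the bounds set for it were met. The 40163 peaks of replicate 1 without a partner had a median strength percentile of 20.9, against 65.1 for the others, and 55.8% overlapped the looser list of replicate 2. But the 6398 such peaks of replicate 2 met the same bounds (15.7 against 53.1, and 50.9% in the looser list of replicate 1). Greater depth of replicate 1 cannot give those, so the test cannot decide on depth. A different mix of cell types stays open. No list of 17 moved beyond the central 99% of matched random lists, the bound set beforehand. That bound was too wide, since the most extreme, the adipocyte list and the stromal and mural list, lay at percentile 99.28 and 5 lists lay outside the central 95%, where chance gives 0.85. The olfactory receptor list, which marks no cell type of the kidney, was among these 5 (98.62).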
